A study of Mus musculus with 6 samples.

How the data were processed

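Total RNA was measured in gonadal somatic cells of XY C57BL/6 mouse embryos at embryonic day E11.5, in 3 libraries labelled Cdyl-Het (heterozygous for a Cdyl deficiency) and 3 labelled Cdyl-KO (homozygous). Per the labels' protocols, cells positive for hCD271, a surface marker in mice of the Nr5a1-hCD271 genotype, were isolated with magnetic beads (MACS), and stranded libraries were made from total RNA with a SMARTer kit for very small inputs (Pico, v2). The labels name the samples as separate samples of a group but do not say whether they came from separate embryos, pools or litters. The p-values therefore measure only the spread between these samples, which may be technical.

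The authors deposited 1 table per library with a gene symbol and a value for each of 11736 genes, the same genes in the same order in all 6. Per the submitters' processing notes, STAR, featureCounts 1.6.4 of the Subread package and the mm10 genome were used. The annotation, the strand setting of the counting, the step from counts to the deposited values and the filter on genes are not given in the sources used here. The deposited values carry no unit in a header or label and were taken as RPKM (reads per kilobase of gene and per 1 M reads of the library), from the values themselves: they were not whole, summed to between 191953 and 209917 per library instead of a fixed total, and were highest for very short genes. Each listed gene had a mean of at least 1.005 in at least 1 of the groups, so genes low in both groups are not analysed here.

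Read depth was worked out from the steps between low values. For short single-exon genes, the value multiplied by the gene's length came in whole multiples of a fixed step in each library. With a tolerance of 0.02 and values of up to 200 reads, 86.4% to 88.1% of low values came out whole, and the steps stood for totals of 34.6 to 45.2 M reads per library. A gene 1 kb long at 1 RPKM then rests on about 34.6 to 45.2 reads. These depths are implied by the values and were not read from a count table. In the miRNA genes given below, every whole count was even. Both reads of a pair may thus have been counted, or the step may be too small. Either way, the number of separate fragments would be lower than these read counts.

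A count model had been planned before the data were examined. Since the values are RPKM, limma 3.58.1 in R 4.3.3 was used instead. Values were divided by a scaling factor per library, a trimmed mean of log ratios against a reference library with 30% of the ratios and 5% of the levels trimmed at each end, without weights, and are called scaled RPKM. The log2 of scaled RPKM plus a pseudocount of 1 was fitted with group as the only term and a spread that depends on level (empirical Bayes with trend), without a further filter on low values. P-values were adjusted by Benjamini-Hochberg over all 11736 genes, with a threshold of 0.05. Fold changes are on the log2(scaled RPKM + 1) scale, which understates the change of weakly expressed genes. Means and SDs are given in scaled RPKM over 3 libraries per group. Changes are given as Cdyl-KO minus Cdyl-Het.

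Before the data were examined, 26 gene lists were fixed, and 24 had the 3 members needed for a test. The mitochondrial genome list had 0 members and the list for neural crest, nerve and muscle cells had too few. Each list was compared with all other genes by camera with the correlation between genes preset at 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run beside it. The genes named were also fixed by rule: Cdyl, 20 genes of gonad development and chromatin whatever their result, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 value of at least 1 and no overlap between groups (leaving out symbols without a proper name), and up to 4 members of each list with the smallest p among those past the threshold. The minimum had been planned in log CPM and was applied to log2(scaled RPKM + 1). Other genes that are named were chosen as members of a fixed list, or after their values were seen where this is stated. Of the 20 genes, Amh and Foxl2 are not analysed here, and not every gene that the rule takes is reported here.

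Positions are those of GENCODE M21, whose build GRCm38 is mm10; 11539 of the symbols (98.3%) matched a single gene. Because the strand setting is not given, genes that overlap the exons of another gene are named as such. The procedure was tested on 5 simulated sets of 11736 genes with 200 changed in each. Limma called 75.2% of genes changed by 0.5 on the log2 scale, 96.4% of those changed by 1 and 97.3% of those changed by 1.5. Of 940 calls, 4.68% were false. The noise was drawn for each gene independently from the spread that limma had fitted, with a single factor per library. It held no correlation between genes and no shift with level, so these rates check the procedure and do not carry over to the real calls. Alternatives fixed before the data were examined were median-ratio scaling, no composition scaling (the deposited values as they are), a replicate block, leaving out each library in turn, thresholds with a fold change of at least 2 or an adjusted p under 0.1, and the other list tests. Alternatives chosen after seeing the data were quantile normalization, pseudocounts of 0.1 and 5, a mean of at least 5 RPKM, robust empirical Bayes, leaving out genes under 300 nt and an adjustment for gene length and GC content. The planned count tools were not run because the values are not counts.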

Results

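The data collected were the RNA profiles of purified gonadal somatic cells from XY embryos at embryonic day E11.5, when the gonad has the capacity to become either testis or ovary and Sry is active. There were 3 Cdyl-Het and 3 Cdyl-KO libraries, and values for 11736 genes. The depth implied by the values was 34.6 M reads in the shallowest library (Cdyl-Het replicate 1) and 45.2 M in the deepest (Cdyl-KO replicate 3). The Pearson correlation of log2 values across genes, which are not independent replicates, was 0.976 to 0.983 between libraries of a group and 0.962 to 0.977 between groups. The first principal component held 42.8% of the variance and separated the groups. The comparison asked how the homozygous deficiency of Cdyl changed gene expression in these cells relative to the heterozygous state. Cdyl encodes a chromodomain protein that binds methylated histone H3 and takes part in transcriptional repression.

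Cdyl itself (chromosome 13, 35659833 to 35874063, mm10) was read in all 6 libraries. Its level was 7.77, 8.06 and 8.22 scaled RPKM in the Cdyl-Het libraries and 6.77, 6.93 and 7.07 in the Cdyl-KO libraries. All 3 Cdyl-KO values lay below all 3 Cdyl-Het values, but the difference did not pass the threshold (log2 change -0.19, SE 0.05, limma adjusted p = 0.0702). On the deposited values without scaling, the change was -0.32 with an adjusted p of 0.0145. The form of the mutation is not given in the sources used here, so reads from outside an altered part of the gene do not check the labels. The related gene Cdyl2 was at 4.73 ± 0.648 and 4.69 ± 0.624 scaled RPKM (SD, n = 3 per group).

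Between the groups, 880 genes changed (limma, adjusted p under 0.05), of which 548 were higher and 332 were lower in Cdyl-KO. They made up 7.50% of the genes. A change of at least 2-fold was reached by 45 of the higher and 30 of the lower genes. All 880 had groups that did not overlap, as did 3707 genes in all (31.6%, where chance gives 10%). The split between higher and lower genes depended on scaling. The median log2 difference of all genes was -0.12 on the deposited values and 0.00 after scaling, and changes are given relative to that shift. On the deposited values, 305 genes were higher and 1558 lower, or 16.4% higher, against 62.3% higher after scaling. After scaling, the median log2 difference was still -0.09 in the lowest and 0.07 in the highest of 4 equal groups of genes by mean level. The count depended on each library: it was 647 without Cdyl-Het replicate 1, 281 without Cdyl-Het replicate 2, 253 without Cdyl-Het replicate 3, 304 without Cdyl-KO replicate 1, 410 without Cdyl-KO replicate 2 and 449 without Cdyl-KO replicate 3.

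**Figure D1:**
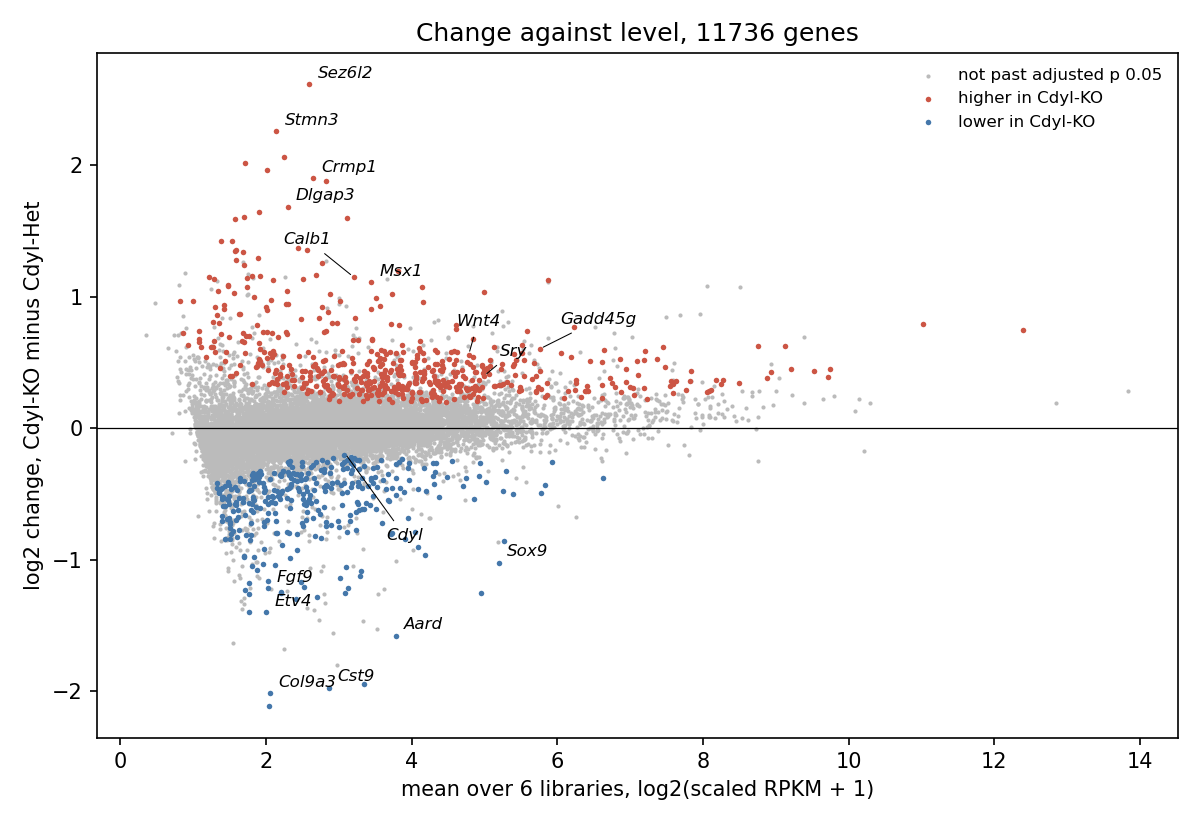
Log2 change (Cdyl-KO minus Cdyl-Het) of each of 11736 genes against its mean over 6 libraries in log2(scaled RPKM + 1). Red points are the 548 genes that were higher in Cdyl-KO and blue points the 332 that were lower, with Sez6l2 at 2.62 at the upper end; on the deposited values without scaling the split was 305 higher and 1558 lower.

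Genes of the testis pathway fell. Of the 19 listed members of this list, 13 were lower in Cdyl-KO, 2 were higher and 4 did not pass the threshold; adjusted over the list alone, 14 were lower and 3 were higher. Sox9, the transcription factor that drives Sertoli cell differentiation (chromosome 11, 112782224 to 112787760), fell from 51.7 ± 7.36 to 25.1 ± 5.36 scaled RPKM (SD, n = 3 per group; log2 change -1.02, SE 0.16, adjusted p = 0.0153). Fgf9, a growth factor needed for testis formation (chromosome 14, 58070547 to 58112720), fell from 5.31 ± 1.28 to 1.70 ± 0.472 (log2 change -1.22, SE 0.18, adjusted p = 0.012). Ptgds, the prostaglandin D synthase of Sertoli cells, changed by -1.23, and Aard, Cst9 and Col9a3, which are expressed in early Sertoli cells, changed by -1.58, -1.97 and -2.02. Cyp26b1, which degrades retinoic acid in the fetal testis, fell from 16.5 ± 2.23 to 9.04 ± 1.47. Sry, the Y-linked switch gene of testis determination (chromosome Y, 2662471 to 2663658), went the other way and rose from 26.7 ± 1.53 to 35.4 ± 2.54 (log2 change 0.40, SE 0.07, adjusted p = 0.0222). Gadd45g, which acts upstream of Sry in XY gonads, rose from 42.9 ± 2.997 to 65.7 ± 3.52 (log2 change 0.60, SE 0.07, adjusted p = 0.00681). Dmrt1, a testis transcription factor, did not pass the threshold (7.14 ± 0.865 and 9.20 ± 0.275, adjusted p = 0.0548). The median log2 change of the list was -0.81 and the list was lower than other genes by camera (adjusted p = 9.08e-07 with the preset correlation), but the adjusted p was 0.504 with an estimated correlation. Markers of endothelial cells moved in the same direction, with a median of -0.43. The number of lower members was 5 without Cdyl-Het replicate 2, 4 without Cdyl-Het replicate 3 and 8 without Cdyl-KO replicate 1, and the adjusted p of Sox9 was then 0.0609, 0.0707 and 0.0531 (0.000641 to 0.0707 over all alternatives). The adjusted p of Sry was 0.0716, 0.0787, 0.0749 and 0.0646 without Cdyl-Het replicate 2, Cdyl-Het replicate 3, Cdyl-KO replicate 1 and Cdyl-KO replicate 3 (0.00349 to 0.0787 over all), that of Fgf9 was 0.0592 without Cdyl-Het replicate 3 (0.000452 to 0.0592 over all). That of Ptgds was 0.0650 without Cdyl-Het replicate 3 (0.000676 to 0.0650 over all) and that of Cyp26b1 was 0.0627, 0.0742 and 0.0532 without Cdyl-Het replicate 2, Cdyl-Het replicate 3 and Cdyl-KO replicate 1 (0.000884 to 0.0742 over all). That of Cst9 was 0.0555 and 0.0683 without Cdyl-Het replicate 2 or 3 (0.00046 to 0.0683 over all) and that of Dmrt1 was 0.0242 without Cdyl-Het replicate 1 (0.0181 to 0.159 over all).

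**Figure D2:**
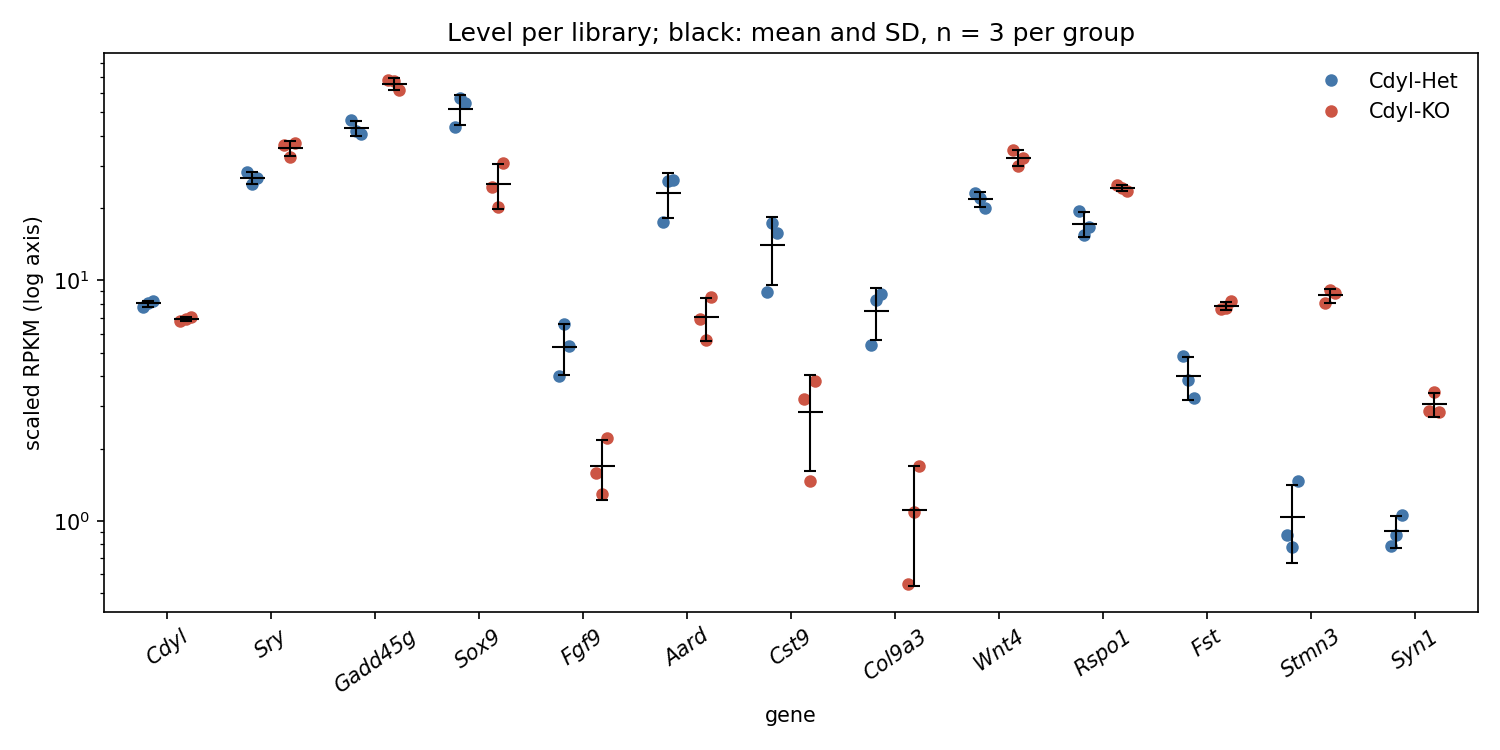
Scaled RPKM on a log axis for 13 genes, with a point for each library (blue Cdyl-Het, red Cdyl-KO) and the mean and SD of 3 libraries per group in black. The groups do not overlap for any gene shown; Sox9, Fgf9, Aard, Cst9 and Col9a3 are lower in Cdyl-KO, while Sry, Gadd45g, Wnt4, Rspo1, Fst, Stmn3 and Syn1 are higher, and Cdyl did not pass the threshold.

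Genes of the ovary pathway rose in the same libraries. Of 14 listed members, 7 were higher in Cdyl-KO, 1 was lower and 6 did not pass the threshold, and the counts were the same when adjusted over the list alone. Wnt4, a signal that promotes ovarian and opposes testicular differentiation (chromosome 4, 137277489 to 137299726), rose from 21.7 ± 1.58 to 32.4 ± 2.52 scaled RPKM (SD, n = 3 per group; log2 change 0.56, SE 0.08, adjusted p = 0.0104). Rspo1, which strengthens Wnt signalling in the ovary, rose from 17.2 ± 1.99 to 24.3 ± 0.793 (log2 change 0.48, adjusted p = 0.0194). Fst, an activin antagonist, rose from 3.99 ± 0.819 to 7.84 ± 0.300, and Msx1, a homeobox factor, rose from 6.42 ± 0.996 to 15.0 ± 0.655. Bmp2, Cdkn1b and Zbtb7c were the other members that rose, with log2 changes of 0.80, 0.44 and 0.43. The list was higher than other genes by camera (median log2 change 0.29, adjusted p = 0.00171 with the preset correlation), but the adjusted p was 0.504 with an estimated correlation. The median of the coelomic epithelium list lay in the same direction (0.33), with 8 members above 0 and 3 below. The number of higher members was 4 when Cdyl-Het replicate 2 or 3 or Cdyl-KO replicate 1 or 2 was left out, and Rspo1 then had an adjusted p of 0.0555, 0.0777, 0.0684 and 0.0589 (0.00215 to 0.0777 over all alternatives). In the same 4 fits Cdkn1b had 0.0582, 0.0544, 0.0562 and 0.0537 (0.00194 to 0.0582 over all). Zbtb7c passed only without Cdyl-Het replicate 1 among the fits that left out a library (up to 0.0777; 0.00349 to 0.0968 over all). No member was lower without Cdyl-Het replicate 2 or 3 (0 of 14).

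Among targets of Wnt/beta-catenin signalling, 4 of 13 listed members rose, 1 fell and 8 did not pass the threshold; adjusted over the list alone, 4 rose and 2 fell. Sp5, a direct target, rose from 3.20 ± 0.238 to 6.49 ± 0.637 scaled RPKM (SD, n = 3 per group; log2 change 0.83, SE 0.08, adjusted p = 0.00375). Tnfrsf19, Lef1 and Axin2 rose by 0.58, 0.49 and 0.32 on the log2 scale, and Ccnd1, which encodes cyclin D1, fell by 0.46. The list as a whole did not pass by camera (adjusted p = 0.258), while fry gave an adjusted p of 0.0377. Without scaling, 3 members rose and 2 fell, and Axin2 did not pass (log2 change 0.19, adjusted p = 0.105; 0.0101 to 0.108 over all alternatives). Leaving out a library gave an adjusted p of 0.0473 to 0.108 for Axin2, which passed only without Cdyl-KO replicate 3, and of 0.00799 to 0.105 for Lef1, which passed only without Cdyl-Het replicate 1; 2 members rose without Cdyl-Het replicate 2 or 3 or Cdyl-KO replicate 1 or 2, and 0 fell without Cdyl-Het replicate 3 or Cdyl-KO replicate 1, where Ccnd1 had 0.0529 and 0.0515.

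Some neuronal genes that are known targets of the repressor REST rose in Cdyl-KO. Of 10 listed members, 5 were higher, 0 were lower and 5 did not pass the threshold. Adjusted over the list alone, 6 were higher and 1 was lower. The list held 24 genes when fixed, and those not in the deposited tables could not be counted. Syn1, Celsr3, Ina, L1cam and Stmn2 had Cdyl-Het means below 1 RPKM, so they are listed only through their level in Cdyl-KO. This filter favours rises in the counts, the median and the list tests. Stmn3, a microtubule-destabilising protein of neurons (chromosome 2, 181306459 to 181314500), rose from 1.04 ± 0.371 to 8.67 ± 0.582 scaled RPKM (SD, n = 3 per group; log2 change 2.26, SE 0.13, adjusted p = 0.000367). Syn1, a synaptic vesicle protein, rose from 0.909 ± 0.139 to 3.05 ± 0.341, and Chga, a protein of secretory granules, from 1.43 ± 0.793 to 4.24 ± 0.145. Kcnh2, a potassium channel, rose from 12.9 ± 0.125 to 20.2 ± 1.25, and Celsr3, a cadherin of axon guidance, from 0.263 ± 0.0850 to 1.48 ± 0.182. Other members were not past the threshold, among them Chgb (2.92 ± 1.52 and 1.29 ± 0.347, adjusted p = 0.145) and Stmn2 (0.899 ± 0.360 and 1.39 ± 0.359, adjusted p = 0.290). The median log2 change was 0.57, and the list was higher by camera (adjusted p = 2.79e-05 with the preset correlation), but the adjusted p was 0.625 with an estimated correlation. Tubb3, a tubulin abundant in neurons and the member of the neural crest, nerve and muscle list that changed, rose from 1.30 ± 0.582 to 4.02 ± 0.707; Hand2, its only other listed member, did not pass the threshold. Without Cdyl-KO replicate 2 or without Cdyl-KO replicate 3, 3 members passed as higher. Celsr3 then missed the threshold (adjusted p = 0.0527 and 0.0551; 0.0013 to 0.0696 over all alternatives) at log2 changes of 0.94 and 0.95, against 0.97 with all libraries. Tubb3 missed it as well (0.0624 and 0.0604; 0.00129 to 0.0624 over all) at 1.06 and 1.12, against 1.15. Chga missed it without Cdyl-Het replicate 1 or any 1 of the Cdyl-KO libraries (0.0589 to 0.0684; 0.00164 to 0.0684 over all) at log2 changes of 1.13 to 1.18, against 1.16.

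The largest rises outside the lists were in genes of low level in Cdyl-Het. Sez6l2, a membrane protein of neurons (chromosome 7, 126950563 to 126970606), had the largest rise under the rule, from 1.44 ± 0.223 to 13.96 ± 0.410 scaled RPKM (SD, n = 3 per group; log2 change 2.62, SE 0.08, adjusted p = 4.03e-05). Vstm2l, Mapk8ip2, Maneal, Crmp1, Soga3, Dlgap3 and Sult4a1 rose by 2.07, 2.02, 1.97, 1.90, 1.88, 1.69 and 1.65 on the log2 scale. Of these, Mapk8ip2 encodes a scaffold of the JNK pathway, Crmp1 a mediator of semaphorin signalling and Dlgap3 a scaffold protein of the postsynaptic density. The largest falls included Kif19a, a kinesin (log2 change -1.40), Etv4, a transcription factor induced by FGF signalling (-1.40), Ptk2b (-1.30), Lrp4 (-1.29) and Mybl1 (-1.26), beside Col9a3, Cst9 and Aard of the testis list. Mybl1 lost its call without Cdyl-Het replicate 3 (adjusted p = 0.0576; 0.00046 to 0.0576 over all alternatives), and Cst9 without Cdyl-Het replicate 2 or 3 (0.0555 and 0.0683). Mir212, Mir6416 and Mir467a-1 also met the rule (log2 changes 1.61, -2.12 and -1.95). The values of Mir212 stood for 2, 4 and 4 reads in Cdyl-Het and 14, 12 and 32 in Cdyl-KO, and those of Mir6416 for 34, 34 and 42 against 0, 16 and 4. Those of Mir467a-1 came to 58.2, 30.2 and 102 against 6, 22.4 and 14 reads, not all of them whole. The whole counts of these 3 genes were all even, so they may stand for fewer separate fragments. Each of the 3 genes lies within another gene (1700016P03Rik, Trpm1 and Sfmbt2). With a library left out, the adjusted p of Mir467a-1 was 0.0505 to 0.151, Mir6416 passed only without Cdyl-KO replicate 2 (up to 0.125) and Mir212 only without Cdyl-KO replicate 2 or 3 (up to 0.0843). Exons of Sez6l2 overlap those of Gm21984, exons of Soga3 those of Gm49353 and Gm9996, exons of Maneal those of Yrdc and exons of Col9a3 those of Tcfl5, and their reads may be shared. Reads may likewise be shared, through overlap or because a gene lies within another, between Syn1 and Araf, Tubb3 and Gm20388, Fst and Gm47040, Axin2 and Gm11670, Lef1 and Gm43352, Ccnd1 and LTO1, and Emx2 and Emx2os. Among the other genes named, this holds for Jund and Gm11175, H19 and each of Mir675, Gm27483 and Gm27786, Nnat and both Blcap and Gm23134, Pax8 and Gm13415, Spp1 and Gm42793, and Celsr3 and Gm23156. It holds as well for Ezh2 and Gm26625, Maf and Gm15655, Hand2 and Hand2os1, Idi1 and Gm48574, and Bhlhe40 and 0610040F04Rik.

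Some factors of the gonadal primordium rose, as did 6 of 11 listed markers of the coelomic epithelium (list median 0.33). Of 22 listed members, 6 rose, 0 fell and 16 did not pass the threshold; adjusted over the list alone, 8 rose and 0 fell. The homeobox factors Emx2 and Lhx9 rose from 53.4 ± 5.47 to 79.5 ± 4.24 and from 23.6 ± 2.84 to 32.7 ± 1.42 scaled RPKM (SD, n = 3 per group; log2 changes 0.57 and 0.46, adjusted p = 0.0129 and 0.0273). Nr0b1, a nuclear receptor, rose from 12.5 ± 0.923 to 18.1 ± 0.741, and Kdm3a, the H3K9 demethylase that activates Sry, from 26.1 ± 1.82 to 36.1 ± 1.99. Nr5a1, whose marker served to isolate the cells, did not pass the threshold (85.8 ± 7.76 and 77.7 ± 7.31, log2 change -0.14, adjusted p = 0.383), nor did Wt1 (70.5 ± 4.93 and 75.9 ± 1.84), Gata4 (79.1 ± 8.20 and 75.1 ± 6.24) or Cbx2 (9.57 ± 0.551 and 10.99 ± 0.674). The list was higher by camera (median log2 change 0.14, adjusted p = 0.00158 with the preset correlation), but the adjusted p was 0.664 with an estimated correlation. By fry it did not pass (adjusted p = 0.0612). Of the 22 members, 21 had a mean of at least 5 RPKM. The highest of the 4 groups of all genes by mean level itself had a median of 0.07, so part of the list's rise may follow level. Without scaling, 5 members rose and 1 fell. Without Cdyl-KO replicate 1, 3 rose, and Kdm3a had an adjusted p of 0.0532 (0.00139 to 0.0532 over all alternatives); Lhx9 lost its call there (0.0874) and without Cdyl-Het replicate 2, Cdyl-KO replicate 2 or Cdyl-KO replicate 3 (0.0688, 0.0624 and 0.0738; 0.00362 to 0.0874 over all).

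Markers of other cell types of the gonad moved in both directions. Of 11 listed genes of the coelomic epithelium, 6 rose, 0 fell and 5 did not pass the threshold (8 rose adjusted over the list alone); Podxl, a sialomucin, rose from 80.7 ± 7.62 to 122 ± 3.68 scaled RPKM and Upk3b, a uroplakin, from 9.30 ± 1.08 to 13.8 ± 0.507 (SD, n = 3 per group). Without scaling, 3 of them rose. Of 10 listed endothelial genes, 4 fell, 0 rose and 6 did not pass the threshold (8 fell adjusted over the list alone); the receptor gene Kdr fell from 10.8 ± 0.639 to 6.91 ± 0.457 and Cdh5, a cadherin of endothelial junctions, from 6.84 ± 0.0966 to 4.38 ± 0.832. Both lists passed by camera (adjusted p = 0.000269 for coelomic epithelium and 1.17e-05 for endothelium with the preset correlation), but for both the adjusted p was 0.504 with an estimated correlation. Of 7 listed erythroid genes, Car2 fell and 6 did not pass the threshold (list adjusted p = 0.0446, and 0.721 with an estimated correlation); the globin Hbb-y was at 61.9 ± 46.1 and 28.6 ± 16.5, with a spread as large as the difference. Of 9 listed genes of the mesonephric epithelium, Calb1 rose from 5.22 ± 0.583 to 12.8 ± 0.899 and Pax8 rose by 0.40 on the log2 scale, while Spp1 fell from 16.6 ± 2.36 to 9.11 ± 0.948 (list adjusted p = 0.833, with a lower direction by camera and a higher one by fry). In the list of interstitial and steroidogenic progenitors, Hsd3b1, an enzyme of steroid synthesis, fell from 4.80 ± 0.383 to 2.33 ± 0.0581 and Maf rose by 0.32. The other 18 of 20 listed members did not pass the threshold (list adjusted p = 0.265). Adjusted over the list alone, 3 of the 20 rose and 5 fell. No member passed in the lists for germ cells (5 listed, list adjusted p = 0.833), meiotic genes (3, 0.544), macrophages and other white cells (3, 0.544), mesenchyme (13, 0.797) and Y-linked genes (4, 0.730). Adjusted over the list alone, however, 2 of the 3 meiotic genes were higher and 1 was lower. Those counts also passed over all genes when genes under 300 nt were left out. In the order Cdyl-Het replicates 1 to 3 and Cdyl-KO replicates 1 to 3 left out, 5, 2, 1, 2, 2 and 2 coelomic genes rose and 1, 2, 2, 1, 2 and 2 endothelial genes fell; 2 endothelial genes fell with quantile normalization. With a library left out, Upk3b lost its call without Cdyl-Het replicate 3 or Cdyl-KO replicate 1 (adjusted p up to 0.0646), Cdh5 kept it only without Cdyl-KO replicate 2 or 3 (up to 0.105), Spp1 lost it without Cdyl-Het replicate 3 (0.0544), Pax8 kept it only without Cdyl-Het replicate 1 (up to 0.0717), Maf only without Cdyl-KO replicate 1 (up to 0.136), and Car2 lost it in all 6 cases (up to 0.106). The erythroid list did not pass without Cdyl-Het replicate 1 or 2 or Cdyl-KO replicate 1 or 2 (0.134 to 0.204). It also did not pass with median-ratio scaling (0.0514), the replicate block (0.0651), quantile normalization (0.115), a mean of at least 5 RPKM (0.127) or fry (0.366), nor on the deposited values (0.474; 0.000195 to 0.721 over all alternatives). On the deposited values, 0 interstitial genes rose and 7 fell.

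**Figure D3:**
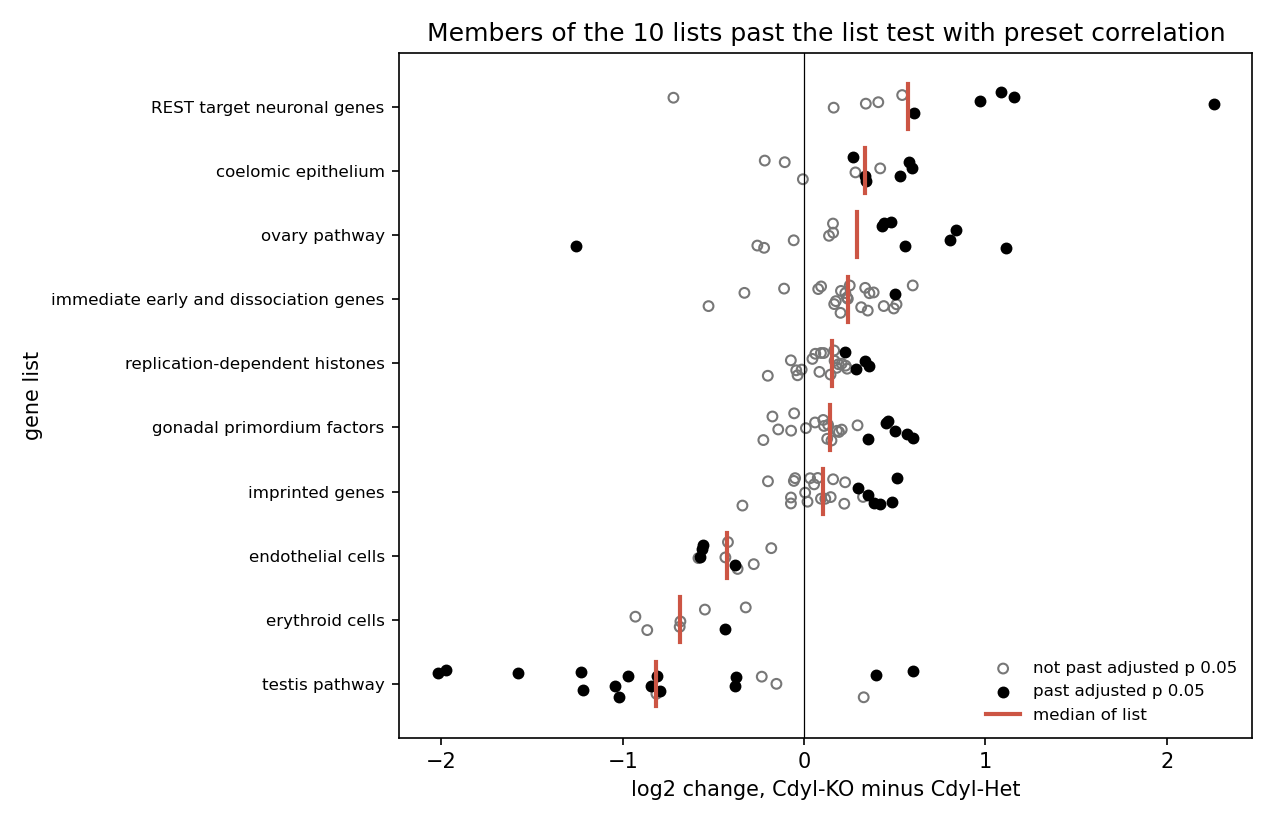
Log2 change (Cdyl-KO minus Cdyl-Het) of each listed member of the 10 lists past the list test with the preset correlation. Filled points passed the adjusted p threshold for the gene, open points did not, and red bars are list medians, from -0.81 for the testis pathway to 0.57 for REST target genes; with an estimated correlation 0 of these lists passed, and quantile normalization turned the direction of the histone list.

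Some genes for chromatin factors rose. Of 24 listed CDYL partners and enzymes of H3K9 and H3K27 methylation, 3 rose, 0 fell and 21 did not pass the threshold (5 rose adjusted over the list alone; list adjusted p = 0.0622). The genes that rose were Kdm3a, the H3K9 methyltransferase gene Ehmt2 (25.1 ± 1.16 to 30.3 ± 0.650 scaled RPKM, SD, n = 3 per group; adjusted p = 0.0322) and Rest (26.7 ± 0.289 to 30.9 ± 0.877; adjusted p = 0.0447). On the deposited values neither Ehmt2 nor Rest passed (adjusted p = 0.117 and 0.371), nor did they pass with any library left out (0.0659 to 0.103 for Ehmt2 and 0.0798 to 0.144 for Rest), and Kdm3a had 0.0532 without Cdyl-KO replicate 1. Over all alternatives the range was 0.0128 to 0.117 for Ehmt2 and 0.0299 to 0.371 for Rest. The list was higher and passed after the length and GC adjustment and without Cdyl-Het replicate 2 (adjusted p = 0.0374 and 0.0168; up to 0.721 over all alternatives). Ezh2, the H3K27 methyltransferase gene, was at 17.2 ± 1.36 and 16.5 ± 0.723 (adjusted p = 0.705).

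Some histone and imprinted genes rose, and so did 1 immediate early gene. The highest of the 4 groups of genes by mean level had a median log2 change of 0.07. Of 22 listed replication-dependent histone genes, 4 rose and 18 did not pass the threshold (4 rose adjusted over the list alone); Hist1h2bj rose from 174 ± 4.20 to 224 ± 5.71 scaled RPKM (SD, n = 3 per group). Their near-identical copies can share reads. Of 24 listed imprinted genes, 6 rose and 18 did not pass the threshold (8 rose and 1 fell adjusted over the list alone), among them Nnat (25.4 ± 2.35 to 35.9 ± 1.35) and H19 (736 ± 46.4 to 962 ± 15.9). Of 23 listed immediate early genes, Jund rose from 81.6 ± 1.49 to 116 ± 9.29 and 22 did not pass the threshold (4 rose and 1 fell adjusted over the list alone). These 3 lists were higher by camera with the preset correlation (adjusted p = 0.00171, 0.00911 and 0.00228), but the adjusted p was 0.664, 0.664 and 0.721 with an estimated correlation. By fry they did not pass (adjusted p = 0.0612, 0.0612 and 0.344). On the deposited values, 1 histone gene rose and 1 fell, 1 imprinted gene rose and 3 fell, and 1 immediate early gene rose and 3 fell. No histone gene rose with quantile normalization (0 of 22, with 1 lower), after the length and GC adjustment (0) or with the replicate block (0), where Hist1h2bj had an adjusted p of 0.186, 0.0558 and 0.0603 (0.00202 to 0.186 over all alternatives). With quantile normalization 3 imprinted genes rose. Quantile normalization turned the histone list to a lower direction (adjusted p = 0.358; 0.000107 to 0.664 over all alternatives) and ended the call of the imprinted list (0.250; 0.00542 to 0.664 over all). In the order Cdyl-Het replicates 1 to 3 and Cdyl-KO replicates 1 to 3 left out, 1, 1, 1, 1, 1 and 2 histone genes and 5, 0, 1, 0, 1 and 1 imprinted genes rose. H19 missed the threshold in each case (0.0536 to 0.0855), on the deposited values (0.0591), with quantile normalization (0.788) and after the length and GC adjustment (0.0716). Nnat missed it without Cdyl-Het replicate 2 or 3 or Cdyl-KO replicate 1 (up to 0.0543). There were 5 immediate early genes that rose without Cdyl-KO replicate 2, and that list had an adjusted p of 0.071 without Cdyl-KO replicate 3.

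Lists for general programmes of the cell did not pass. The lists for proliferation (24 listed, adjusted p = 0.265), Hox genes (24, 0.519), p53 targets (14, 0.730), cholesterol synthesis (21, 0.487; Idi1 rose by 0.51) and glycolysis and hypoxia (22, 0.193; Aldoa rose by 0.45 and Bhlhe40 fell by 0.55) were not past the threshold. The proliferation list was lower and passed on the deposited values, with quantile normalization, with a mean of at least 5 RPKM and without Cdyl-Het replicate 3 (adjusted p = 0.0241, 0.00492, 0.0391 and 0.00975; up to 0.845 over all alternatives), and 7 of its members fell on the deposited values, as did 3 Hox genes and 3 p53 targets. The Hox list passed without Cdyl-Het replicate 2 (0.0492; up to 0.891 over all). Idi1 and Bhlhe40 kept their calls only without Cdyl-Het replicate 1 among the fits that left out a library (up to 0.0809 and 0.0986), and quantile normalization ended that of Aldoa (0.0664).

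Of the 24 lists tested by camera with the preset correlation, 7 were higher and 3 were lower in Cdyl-KO. With an estimated correlation, 0 lists passed and the lowest adjusted p was 0.504, while 1 list, that of endothelial cells, had an unadjusted p under 0.05. By fry, 6 lists passed.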

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

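Quantile normalization, pseudocounts of 0.1 and 5, a mean of at least 5 RPKM, robust empirical Bayes, leaving out genes under 300 nt and an adjustment for gene length and GC content were chosen after seeing the data; the other alternatives were fixed before. The number of genes changed was 880. It was 1863 without composition scaling (637 of them shared), 1443 without genes under 300 nt (836 shared), 1683 at an adjusted p under 0.1 and 75 with a fold change of at least 2, and lay between 703 and 1093 with the other scalings, pseudocounts, filters and corrections. With the replicate number as a block (replicate block) it was 337, of which 328 were shared. The plan had no pairs, because the labels do not say what a number shares. Libraries with the same number did not deviate together (correlations across genes of -0.05, -0.27 and -0.05), and 0 of 6 libraries deviated most like the library of its own number. With 3 libraries per group this is a weak check of pairing. Leaving out a library gave between 253 (without Cdyl-Het replicate 3) and 647 (without Cdyl-Het replicate 1) genes; these fits hold fewer samples.

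Cdyl was lower in every alternative run; it passed only without composition scaling (log2 change -0.32, adjusted p = 0.0145), and its adjusted p was 0.0558 to 0.193 in the others. The number of lists changed was 10; it was 0 with an estimated correlation and 6 with fry, and 8 to 11 elsewhere. The testis and ovary lists passed in every alternative run on the lists except the estimated correlation, where both had an adjusted p of 0.504; robust empirical Bayes was not run on the lists. The list of replication-dependent histones reversed with quantile normalization (adjusted p = 0.358); the cause was not tested for any of these changes other than fewer samples or another threshold. Of the 71 named genes that passed, 11 did not pass without composition scaling, 13 with quantile normalization, 28 with the replicate block, 9 after the length and GC adjustment and 16 to 32 when a library was left out; 0 reversed. An unfiltered fit gave no value, as no filter was added to that of the deposited tables, and the planned DESeq2, edgeR and limma-voom fits were not run because the values are not counts. Depth limits short genes most: a gene of 1 kb at 1 RPKM rests on 34.6 to 45.2 reads, and a shorter gene on fewer in proportion. The number of separate fragments may be lower still.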

Other observations

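The gene lists of this part were written after the results had been seen, and the tests reported here were chosen after the result was seen, except for other splits of the libraries and the calls near Cdyl, which were set before. The tests of gonadal somatic cells, neural cells and abundant genes were redefined after earlier versions of each had been computed. The genes named here were chosen after their values were seen. P-values of the lists written for this part were adjusted over these 6 lists only, apart from the fixed lists. They are thus not comparable with the adjusted p-values of the fixed lists. By camera with an estimated correlation, the fixed endothelial list had an unadjusted p of 0.0258 and an adjusted p of 0.504. The list of synapse, vesicle and channel genes given below had 0.0277 and 0.118. Some genes induced by FGF and ERK signalling were lower in Cdyl-KO. Of 13 listed, 7 fell, 0 rose and 6 did not pass the threshold (7 fell adjusted over the list alone; camera adjusted p = 3.23e-06 with the preset correlation, and adjusted p = 0.134 with an estimated correlation). Etv4 fell from 5.51 ± 0.375 to 1.502 ± 0.494 scaled RPKM, Etv5 from 19.2 ± 2.53 to 10.3 ± 1.66, Spry4 from 6.16 ± 1.06 to 2.61 ± 0.509 and Dusp6, a phosphatase that limits ERK, from 29.5 ± 2.28 to 21.5 ± 1.13 (SD, n = 3 per group). Of the 13, 1 is also on the testis list (Etv5) and 1 on the Wnt list (Ccnd1). FGF signalling itself was not measured. Collagens and matrix genes typical of cartilage also fell, 5 of 8 listed with 0 higher (adjusted p = 3.20e-05, and 0.134 with an estimated correlation). Col2a1 fell from 4.12 ± 0.461 to 1.29 ± 0.490 and Col27a1 from 7.80 ± 1.43 to 2.80 ± 0.651. Col2a1 is a known target of SOX9, and 1 of the 8 is also on the testis list (Col9a3). Of the FGF list, 3, 2 and 4 members fell without Cdyl-Het replicate 2, Cdyl-Het replicate 3 and Cdyl-KO replicate 1, and of the cartilage list 3 fell without Cdyl-Het replicate 3. Without Cdyl-Het replicate 3, the adjusted p was 0.0645 for Etv5, 0.0664 for Dusp6 and 0.0544 for Col2a1. Etv5 also missed the threshold without Cdyl-Het replicate 2 (0.0517) and Dusp6 without Cdyl-Het replicate 2, Cdyl-KO replicate 1 or Cdyl-KO replicate 2 (0.0630, 0.0587 and 0.0565). Over all alternatives the range was 0.00059 to 0.0645 for Etv5, 0.00197 to 0.0664 for Dusp6 and 0.000421 to 0.0544 for Col2a1. Of 9 listed genes of adrenal-type steroid synthesis, 5 of them also on the interstitial list, which did not pass (adjusted p = 0.265), Hsd3b1 and Akr1b7 fell (log2 changes -0.80 and -0.78) and 7 did not pass the threshold (5 fell adjusted over the list alone; adjusted p = 0.000186, and 0.118 with an estimated correlation); 1 fell without Cdyl-Het replicate 3 or any of the Cdyl-KO libraries, and 5 fell on the deposited values. Among the fits that left out a library, Akr1b7 passed only without Cdyl-Het replicate 2 (up to 0.152; 0.00845 to 0.152 over all alternatives).

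Some genes of synapses, vesicles and ion channels were higher. Of 42 listed members of these families, of which 2 are also on the REST list (Syn1 and Kcnh2), 20 rose, 0 fell and 22 did not pass the threshold (21 rose adjusted over the list alone; camera adjusted p = 1.24e-09 with the preset correlation, and 0.118 with an estimated correlation). Syt7, a calcium sensor of vesicle fusion, rose from 4.19 ± 0.333 to 9.52 ± 0.472 scaled RPKM and Cplx2 from 4.32 ± 0.233 to 8.81 ± 0.205 (SD, n = 3 per group). The list held 84 genes when written, and those not in the deposited tables could not be counted. The filter on level may favour rises here, as in the REST list. As the list was written after such rises had been seen, its test is not independent evidence of its direction. On the deposited values 18 rose and 1 fell. Reads may be shared between Syt7 and Gm26859, Akr1b7 and Gm13857, Nefm and Nefl, Nsg1 and Stx18, and Uchl1 and Uchl1os, whose exons overlap.

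A first pattern is that genes downstream of Sry fell while Sry rose. A lower share of gonadal somatic cells in the Cdyl-KO preparations would lower Nr5a1, Wt1 and Gata4 by about the -0.81 of the testis list. Their median log2 change was -0.07 (-0.0712) and the lowest -0.14, which argues against a lower share as the whole cause of the fall. A smaller loss of gonadal somatic cells is not excluded (Nr5a1 -0.14, SE 0.09). On the deposited values, which carry the shift of all genes, Nr5a1 had means of 90.3 in Cdyl-Het and 73.8 in Cdyl-KO. Gata4 had 83.2 and 71.4, and Wt1 74.2 and 72.1. These markers cannot show a change in the make-up of the gonadal somatic cells themselves, which was not tested and stays open. An XX embryo among the Cdyl-KO libraries would lower the Y-linked genes. The lowest sum of 4 Y-linked genes in a Cdyl-KO library was 0.943 of the Cdyl-Het mean, which argues against a library from XX embryos alone. The labels do not say whether the samples were pools, and a small share of XX cells in a pool would not show. A difference of some hours in age cannot be told apart from the genotype: 6 genes that fall with embryonic age had a median log2 change of 0.0996, with 0 past the threshold, and as a list they were higher by fry (adjusted p = 0.0266) but not past the threshold by camera (0.117 with the preset and 0.224 with an estimated correlation). The homozygous deficiency of Cdyl, acting between Sry and Sox9 or through a delay, stays open and was not tested.

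A second pattern is the rise of some neuronal genes. Neural cells in the Cdyl-KO preparations would bring all the transcripts abundant in embryonic neurons. The MACS selection for hCD271 would be expected to remove most such cells, but how far it did is not known. Markers of other cells were still read, with Kdr at 10.8 and Hbb-y at 61.9 scaled RPKM in Cdyl-Het. Endothelial markers were also lower in Cdyl-KO (median log2 change -0.43, with 4 of 10 past the threshold). Among genes with a mean under 5 scaled RPKM, 9 transcripts abundant in embryonic neurons had a median rise of 0.325 RPKM (quartiles -0.212 and 0.604). Of these 9, 4 were lower in Cdyl-KO. The 4 risen REST-list genes of that range had a median rise of 2.48 RPKM. They were picked because they rose, and the level of each gene in neurons was not measured, so the medians cannot decide. The neuron transcripts did not rise evenly. Stmn2, Gap43 and Uchl1 were at 0.899, 2.02 and 3.66 in Cdyl-Het and 1.39, 1.38 and 3.63 in Cdyl-KO. Tubb3 rose by 2.72 RPKM. At 5 RPKM or more, 7 of the neuron transcripts had a median rise of 4.29 RPKM, against 7.31 for Kcnh2, the only risen REST-list gene there. Neural cells and a rise within the gonadal cells thus cannot be told apart in either range. Of all 16, Nefm, Map1b, Nsg1 and Tubb3 rose and 12 did not pass the threshold (list adjusted p = 0.000186 by camera, and 0.134 with an estimated correlation). Nsg1 had an adjusted p of up to 0.0727 with a library left out. After adjustment for gene length and GC content, 5 of the 5 risen REST-list genes still passed, which argues against these biases as the whole cause. A candidate explanation is relief from repression by CDYL, which is known to act with REST; binding was not measured here, so this stays a hypothesis.

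Another pattern is the lower median of all genes in Cdyl-KO before scaling. Reads in the 11539 listed genes with a matched length made up 66.6% to 69.6% of the implied total in Cdyl-Het and 62.5% to 64.6% in Cdyl-KO. The lengths are those of GENCODE M21, and the submitters' annotation is not known. The log2 ratio of these shares was -0.0969, against a median shift of -0.123. A larger share of reads outside these 11539 genes could thus account for most of the shift. The shift was -0.125 with the 50 genes of most reads taken out of each library total, so these 50 do not explain it. The 197 genes without a matched length could not be among them, and other cuts were not tried. The 50 highest values of each library made up 25.1% to 26.0% of its summed RPKM in Cdyl-Het. In Cdyl-KO they made up 28.0% to 30.5%. What the other reads came from (ribosomal RNA, introns, genes not listed or listed genes without a matched length) is open, as is whether the cause lies in the libraries or in the cells.

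Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real split, gave as many as 880 changed genes, and the highest of the others gave 4; with 10 splits the share cannot fall under 0.05. Within 10 Mb of Cdyl, 4 of 58 listed genes changed (6.90%), against 7.47% elsewhere (Fisher's exact test, two-sided, p = 1).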
